A study of Rattus norvegicus with 14 samples.

How the data were processed

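Total RNA from 14 cultures of primary rat cortical neurons was measured, 1 culture per array, on the Affymetrix rat transcriptome array, which carries probes against coding and noncoding transcripts grouped into transcript clusters. Per the labels' protocols, the neurons came from cortices of Sprague Dawley embryos, received lentivirus on the day of plating, had part of the medium exchanged on day 3 and were harvested on day 6 in vitro. Samples were grouped from their titles into non-targeting shRNA (n = 3), Rbm5 shRNA (n = 3), empty vector (n = 4) and Rbm5 overexpression (n = 4). The shRNA vectors carried green fluorescent protein and were used at a multiplicity of infection of 60, and the other vectors at 30. The overexpression vector held the rat Rbm5 open reading frame with a DDK tag. Per the labels, replicates of a group were separate cultures, prepared from different pregnant rats on different days, so the spread between arrays of a group includes that between cultures.

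The deposited table holds 1 value per transcript cluster and array, taken as log2, made by the authors with robust multi-array average (RMA) in Affymetrix Expression Console, per the submitters' processing notes. The log base is not given in the sources used here. It was taken as log2 because that is what RMA gives and because the values of transcript clusters run from 1.79 to 19.9315, an upper limit reached by 37 clusters on at least 1 array. The background option, the annotation build, the software version and which arrays were normalized together are likewise not given in the sources used here. Changes near the upper limit are understated, and 181 of the clusters tested held a value above 19. Array medians over the kept clusters lay between 7.1277 and 7.3096, so the deposited values had not been forced to a common distribution at this level.

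Of 70580 rows, 1738 were control rows and 68842 were transcript clusters. Clusters with a mean of at least 5 over all 14 arrays were kept, which left 28976. Names came from the platform's annotation table, which gave 1 gene symbol for 23446 clusters, several for 505 and none for 44891, and 1 symbol was updated through its Entrez number. Of the kept clusters, 13177 had 1 symbol, covering 12583 distinct symbols. A cluster with several symbols or none was counted but not named. No coordinates are given, since the annotation build is not given in the sources used here. The precision of every comparison is limited by the number of arrays, and no read depth applies to this assay.

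All 14 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group and a variance trend in eBayes, which left 10 residual and 3 prior degrees of freedom. The comparisons were Rbm5 shRNA minus non-targeting shRNA, Rbm5 overexpression minus empty vector, the difference of these effects, and non-targeting shRNA minus empty vector. In the last of these, vector and dose of virus change together. Whether groups shared preparation days is not given in the sources used here. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the kept clusters, and the threshold was an adjusted p of 0.05. Errors of log2 changes are standard errors (SE) from limma, and errors of group means are standard deviations (SD). Exact permutation tests of the arrays were run for Rbm5 and for the control probes.

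Gene lists were fixed before the data were examined: splicing regulators and spliceosome, nonsense-mediated decay factors, apoptosis, p53 targets, interferon and antiviral response, excitatory cortical neuron and postsynaptic genes, inhibitory neuron genes, synaptic vesicle and release genes, voltage-gated ion channels, neurite growth and neuronal cytoskeleton, activity-regulated immediate early genes, astrocyte, oligodendrocyte lineage, microglia, and vascular and fibroblast markers, proliferation and neural progenitor genes, the unfolded protein, heat shock and amino acid stress response, cholesterol synthesis, the mitochondrial respiratory chain, and the chromosomal neighbourhood of Rbm5. Each symbol was represented by its brightest kept cluster, and a list needed 5 members, so that 19 of 20 lists were tested. Lists were tested against all other symbols so represented, with limma's camera at a preset correlation of 0.01 between genes. Clusters with several symbols or none did not enter these tests. A correlation estimated per list was used beside the preset one, and both were adjusted over the lists of a comparison. Limma's fry was run as a further list test, and its p is given unadjusted. Within a list, members past the threshold were counted after adjustment over all clusters and after adjustment over the list alone.

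The genes named in a comparison were chosen by a rule fixed before the data were examined, among kept clusters with 1 symbol, leaving out placeholder symbols and small RNAs. It takes Rbm5, Rbm6 and Rbm10, then up to 12 rises and 12 falls, the largest past the threshold whose arrays do not overlap between the groups. Where fewer than 4 passed in a direction, clusters with the smallest p filled up to 4. It then takes up to 4 members with the smallest p from each list that camera called, and up to 2 members past the threshold from other lists. Genes past the threshold in both the knockdown and the overexpression complete it. Genes named outside this rule are identified where they appear.

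The fit was tested on simulated arrays with 200 changed clusters among 28976 before use. Their noise was independent between clusters, with 1 SD per cluster for all groups, so variation shared by many clusters was not simulated. For the knockdown it called 17.9%, 68.7% and 95.5% of clusters changed by 0.5, 1 and 2 on the log2 scale, with 3 unchanged clusters called. For the overexpression the shares were 46.3%, 79.1% and 98.5% with 7 unchanged clusters called, for the difference of effects 13.4%, 49.3% and 86.4% with 9, and for the control vectors 23.9%, 70.1% and 95.5% with 5.

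Alternatives chosen before the data were examined were a fit on the arrays of the compared groups alone, the replicate number as a block, no filter and a stricter filter at a mean of 6, clusters with 1 symbol only, quantile normalization, centring on the array median, eBayes without a trend or with robust variances, array weights, other thresholds, and leaving out each array in turn. Alternatives chosen after seeing the data were a covariate made of the difference between the medians of positive and negative control rows of each array, the empty vector as the control for Rbm5 shRNA, and a call against both controls. Where comparisons shared arrays, 100 simulations without any effect gave the correlation that the shared arrays alone produce. Hardly any cluster is called in such simulations, so their overlap of calls is no yardstick for the observed overlap. Other splits of the arrays into groups of the same sizes were counted, all of them or 100 drawn with a fixed seed.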

Results

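Gene expression was measured in primary cortical neurons of Sprague Dawley rat embryos in which the amount of Rbm5, an RNA-binding protein that takes part in pre-mRNA splicing, had been lowered or raised with lentivirus from the day of plating until day 6 in vitro. Of 14 arrays, 3 came from cultures with a short hairpin RNA (shRNA) against Rbm5, 3 from cultures with a non-targeting shRNA, 4 from cultures with an Rbm5 overexpression vector and 4 from cultures with the empty vector. Both shRNA groups received virus at a multiplicity of infection of 60 and the other groups at 30. The values are RMA signals taken as log2, a base that is not given in the sources used here, with 28976 transcript clusters bright enough to test. No arrays held identical values, and correlations between arrays of a group ran from 0.9853 to 0.9975.

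Rbm5 itself was lowest in every Rbm5 shRNA array and highest in every overexpression array. Its mean signal was 8.35 ± 0.10 (SD, n = 3) with Rbm5 shRNA against 10.82 ± 0.011 (n = 3) with non-targeting shRNA, a change of -2.48 (SE 0.11, limma adjusted p = 1.64e-07) that left 17.9% of the control level. With the overexpression vector the mean was 12.02 ± 0.17 (n = 4) against 10.50 ± 0.035 (n = 4) with the empty vector, a rise of 1.52 (SE 0.092, adjusted p = 1.28e-05) or 2.87-fold. The exact two-sided permutation p was 0.1 for the knockdown and 0.0286 for the overexpression, each the smallest that these group sizes allow. Rbm6, the neighbouring paralog, and Rbm10, a further paralog, did not pass the threshold in either comparison: Rbm6 had changes of -0.18 (adjusted p = 0.36) in the knockdown and 0.085 (adjusted p = 1) in the overexpression, and Rbm10 of 0.047 (adjusted p = 0.907) and -0.068 (adjusted p = 1). Between the control vectors, Rbm5 was 0.32 higher with non-targeting shRNA (adjusted p = 0.0893, exact permutation p = 0.0286).

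**Figure D1:**
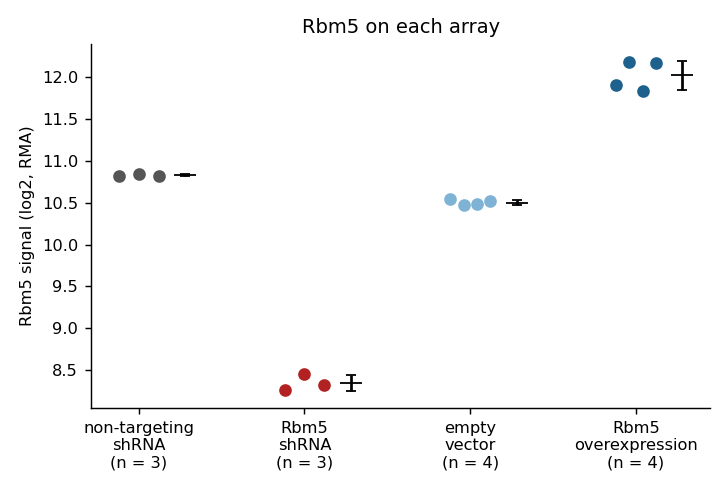
Rbm5 signal (log2, RMA) on each of the 14 arrays by group, with points for arrays and bars for the group mean and SD. The 3 Rbm5 shRNA arrays lie between 8.262 and 8.457 and the 4 overexpression arrays between 11.84 and 12.18, with the control arrays between 10.47 and 10.84.

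The arrays also differed in ways that the amount of Rbm5 did not follow. The first principal component held 41.4% of the variance and the second 16.5%. On the second component the non-targeting arrays lay at -27.4 ± 1.7 (SD, n = 3), below each of the other 11 arrays, against -2.79 ± 16 for Rbm5 shRNA, 10.1 ± 9.7 for the empty vector and 12.6 ± 19 for the overexpression. The single Rbm5 shRNA arrays lay at 15.81, -11.2 and -12.97. The lowest array of the empty vector and overexpression groups lay at -4.877. The first component followed a measure of array quality, the difference between the medians of positive and negative control rows, across all 14 arrays (Pearson r = 0.824, permutation p = 2e-04, Spearman rho = 0.815, permutation p = 6e-04). The relation held without the 2 arrays farthest from the median of that measure (r = 0.761) and for deviations from the group means (r = 0.903). Group means of the measure ran from 4.91 to 5.08, and exact permutation tests gave p = 0.6 for Rbm5 shRNA against non-targeting shRNA and p = 0.514 for the overexpression against the empty vector.

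**Figure D2:**
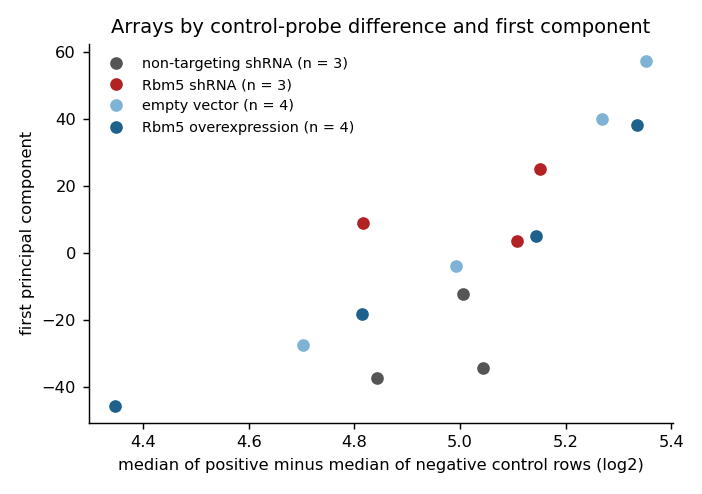
First principal component of the kept transcript clusters against the difference between the medians of positive and negative control rows (log2), with 1 point per array and colours for the groups. The measure ran from 4.3472 in an overexpression array to 5.3528 in an empty vector array, and r was 0.824.

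Against non-targeting shRNA, 730 transcript clusters differed in Rbm5 shRNA cultures, 390 higher and 340 lower, 90 and 53 of them by 2-fold or more. The highest named rises were Uchl3, a ubiquitin hydrolase (2.21, SE 0.19, adjusted p = 8.91e-05, and 1.03, SE 0.12, adjusted p = 0.000847 on a further cluster of the gene), Pfn2, a neuronal profilin that binds actin (1.98, SE 0.18), and Fam3c, a secreted protein (1.88, SE 0.15). They were followed by Rgs4, which shortens G protein signals (1.70), Tprg1l (1.69), the endosomal GTPase Rab4a (1.63), Tmbim6, an anti-apoptotic protein of the endoplasmic reticulum (1.62), the importin Ipo5 (1.60), Tbc1d24 (1.55), the metalloproteinase Mmp24 (1.51), Sema3c, a secreted guidance cue (1.5), and Cpne8 (1.49). Below Rbm5, the largest falls were those of Plekhb2 (-1.87, SE 0.29, adjusted p = 0.00406), the gamma-tubulin complex factor Mzt2b (-1.65, SE 0.17, adjusted p = 0.000265) and Txnip, a thioredoxin-binding protein (-1.52, SE 0.35, adjusted p = 0.0374). Gpc2 (-1.48), Slc25a2 (-1.47), the cadherin Cdh12 (-1.44), St6galnac5 (-1.38), Rgs13 (-1.34), the adhesion molecule Alcam (-1.31), Ptpn4 (-1.29) and the dopamine receptor Drd2 (-1.26) also fell. Groups did not overlap for 27.4% of all clusters, where chance gives 10%, and 4373 had an unadjusted p under 0.05 against 1449 by chance. The share of calls that were higher was 53.4%, but 71.8% after quantile normalization, 76.1% after median centring, 39.2% with only the arrays of these groups, 40.4% with a control-probe covariate (added after seeing the data) and 42.9% with array weights. Without non-targeting array 1, 2 or 3 the count was 322, 310 or 392, and without Rbm5 shRNA array 1, 2 or 3 it was 417, 473 or 337.

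Most of these differences lay in the non-targeting cultures rather than in the Rbm5 shRNA cultures. Uchl3 was at 10.28 ± 0.28 (SD, n = 3) with non-targeting shRNA, but at 12.50 ± 0.31 with Rbm5 shRNA, 12.49 ± 0.19 with the empty vector and 12.56 ± 0.22 with the overexpression. For Cdh12 the non-targeting mean was 9.35 ± 0.32 against 7.91 ± 0.31, 7.36 ± 0.31 and 7.52 ± 0.11 in the same order. In 585 of the 729 clusters called besides Rbm5 (80.2%), the Rbm5 shRNA mean was nearer the empty vector than the non-targeting mean was. Against the empty vector, a comparison added after seeing the data in which dose and vector also differ, the changes of Tprg1l (-0.13), Tmbim6 (-0.11), Mmp24 (-0.094), Cpne8 (-0.086), Drd2 (0.15), Rgs13 (0.12), Cdh12 (0.55) and Txnip (0.24) had the opposite sign and did not pass. Uchl3 (0.00084), Pfn2 (0.12), Fam3c (0.32), Rgs4 (0.69), Rab4a (0.078), Ipo5 (0.34), Tbc1d24 (0.061), Sema3c (0.91), Gpc2 (-0.0095), Slc25a2 (-0.94), St6galnac5 (-0.020), Alcam (-0.22) and Ptpn4 (-0.47) kept their sign and did not pass either. Slc25a2 (limma adjusted p = 0.0533) and Sema3c (adjusted p = 0.127) differed from the rest. Their Rbm5 shRNA means lay farther from the empty vector than the non-targeting means did (0.53 and -0.59). Leaving out a single array ended the calls of Ptpn4, St6galnac5 and Txnip, for Txnip in 7 of the 14 cases.

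**Figure D3:**
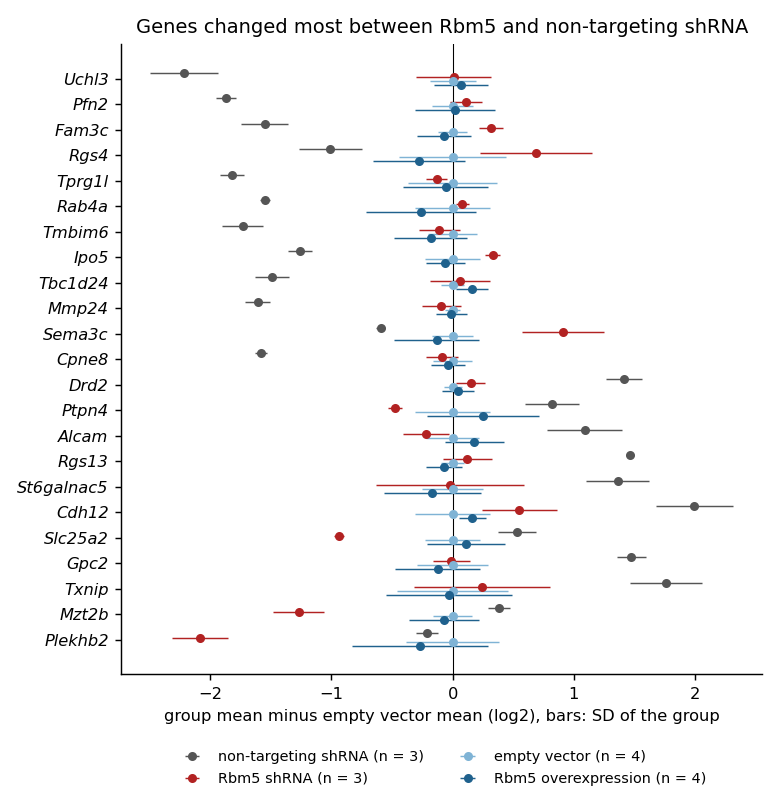
Group means relative to the empty vector mean (log2), with bars for the SD of each group, for the 12 largest rises and the 11 largest falls besides Rbm5 that the naming rule takes from the knockdown. Non-targeting shRNA stands alone for genes such as Uchl3 (10.28 against 12.49 to 12.56 in the other groups), while Plekhb2 and Mzt2b stand apart in Rbm5 shRNA.

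Besides Rbm5, 26 clusters differed in Rbm5 shRNA cultures from both control groups in the same direction, 20 lower and 6 higher, and all 26 also differed that way from the overexpression arrays. That adds little, since the overexpression arrays differed from the empty vector arrays in Rbm5 alone and the same Rbm5 shRNA arrays were used. Of the genes the naming rule takes, Plekhb2 changed by -2.08 (SE 0.27, adjusted p = 0.0082) and Mzt2b by -1.27 (SE 0.15, adjusted p = 0.00525) against the empty vector, while the splicing helicase Dhx15 rose by 0.64 (SE 0.085, adjusted p = 0.00904) against the empty vector and by 0.40 (SE 0.091, adjusted p = 0.0356) against non-targeting shRNA. The following genes were named after their values were seen. Pdpk1, the kinase that activates Akt, changed by -1.17 (adjusted p = 5.57e-05) against non-targeting shRNA and by -0.92 (adjusted p = 0.0014) against the empty vector. The receptor phosphatase Ptprf (-0.95 and -1.16), the LIM-domain cofactor Ldb2 (-1.20 and -0.92), Klhl7 (-1.22 and -0.97), Cbfb, a partner of Runx factors (-0.68 and -1.09), the AMPA receptor regulatory protein Cacng3 (-0.75 and -1.06) and the matrix protein Tnc (-1.04 and -1.94) were likewise lower than in both controls. The histone methyltransferase Ehmt2 (0.58 and 0.69), the sialyltransferase St3gal1 (0.64 and 0.61), Minar2 (0.63 and 0.58), Hmgcll1 (0.89 and 0.79) and Guf1 (0.48 and 0.85) were higher. These comparisons share the Rbm5 shRNA arrays. Simulations without any effect gave an overlap of 0, but with hardly anything to call they cannot show what the shared arrays add. Independent sets of the observed sizes would share 0.452, and part of the excess over that may come from the shared arrays. Across clusters the r of the 2 comparisons was 0.172 against a simulated 0.534, and their covariance 0.00986 against 0.0247. Genes are not independent replicates in such a correlation.

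**Figure D4:**
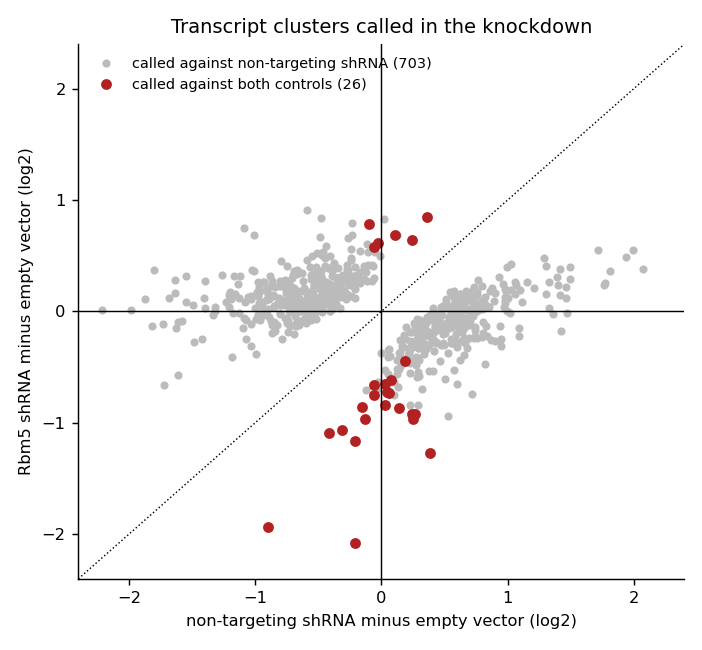
Rbm5 shRNA minus empty vector against non-targeting shRNA minus empty vector (log2) for the 729 transcript clusters besides Rbm5 called in the knockdown, 1 point each, with a dotted line where both shRNA groups are equal. Points called against both controls (26) are in colour, and the other 703 spread mainly along the horizontal axis.

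Among the gene lists, cholesterol synthesis was shifted upward in the knockdown, with all 19 tested members positive and a median of 0.42 (camera adjusted p = 0.000352). Its adjusted p was 0.976 with an estimated correlation, and fry gave it an unadjusted p of 0.106. No member passed over all genes and 4 rose when adjusted over the list alone. Its leading members were Hsd17b7 (0.89, adjusted p = 0.0921), the cholesterol carrier Stard4 (0.65, adjusted p = 0.155), Ebp (0.60, adjusted p = 0.138) and Fdps (0.42, adjusted p = 0.159), and against the empty vector the median was 0.048 (camera adjusted p = 0.672). Of 23 p53 targets, 3 rose over all genes and 6 rose and 1 fell when adjusted over the list alone (list adjusted p = 0.0581), with examples in Zmat3 (0.79) and the cell cycle inhibitor Cdkn1a (0.68). Fry gave the p53 targets an unadjusted p of 0.0176, the lowest of the 19 lists. Of 28 excitatory and postsynaptic genes 3 rose, 4 up and 1 down when adjusted over the list alone (list adjusted p = 0.917), among them the calmodulin-binding Nrgn (0.79) and the scaffold Homer1 (0.73). Of 37 ion channel genes 2 rose, 4 up and 3 down when adjusted over the list alone (list adjusted p = 0.945): Scn3b, a sodium channel subunit (1.19), and Kcnip4 (0.56). Of 31 neurite genes 3 rose and 1 fell, 3 up and 2 down when adjusted over the list alone (list adjusted p = 0.695), with Cntn1 (0.77) and the growth cone protein Gap43 (0.71) among the rises. Of 34 synaptic vesicle genes, Sv2b (0.85) alone rose, and it alone when adjusted over the list alone (list adjusted p = 0.501). Of 18 immediate early genes Egr1 rose (0.93) and Fosl2 fell (-0.59), with 1 up and 1 down when adjusted over the list alone (list adjusted p = 0.346). Of 69 splicing genes 1 rose and 2 fell, 2 up and 4 down when adjusted over the list alone (list adjusted p = 0.136), with Dhx15 (0.40) and the neuronal splicing factor Nova1 (-0.41) as examples. Of these members, Dhx15 alone also passed against the empty vector, where Zmat3 (-0.015) and Fosl2 (0.15) had the opposite sign, and leaving out single arrays ended the calls of Cntn1, Gap43, Kcnip4, Dhx15, Nova1 and Fosl2.

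No member passed over all genes in the other lists. When adjusted over the list alone, 2 inhibitory neuron genes rose and 1 fell of 18 (list adjusted p = 0.387), 1 oligodendrocyte lineage marker fell of 13 (list adjusted p = 0.387), and none passed among 21 astrocyte markers (list adjusted p = 0.945), 7 vascular and fibroblast markers (0.945), 32 apoptosis genes (0.858), 16 interferon genes (0.173), 18 nonsense-mediated decay factors (0.395), 29 proliferation genes (0.695), 22 stress response genes (0.367), 37 respiratory chain genes (0.945) and 19 genes around Rbm5 on its chromosome (0.945). The median, mean and camera direction differed in sign for 5 of the 18 lists without a call: apoptosis, excitatory genes, ion channels, vascular markers and the respiratory chain. Only 2 microglia markers were bright enough to keep, too few for a test.

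**Figure D5:**
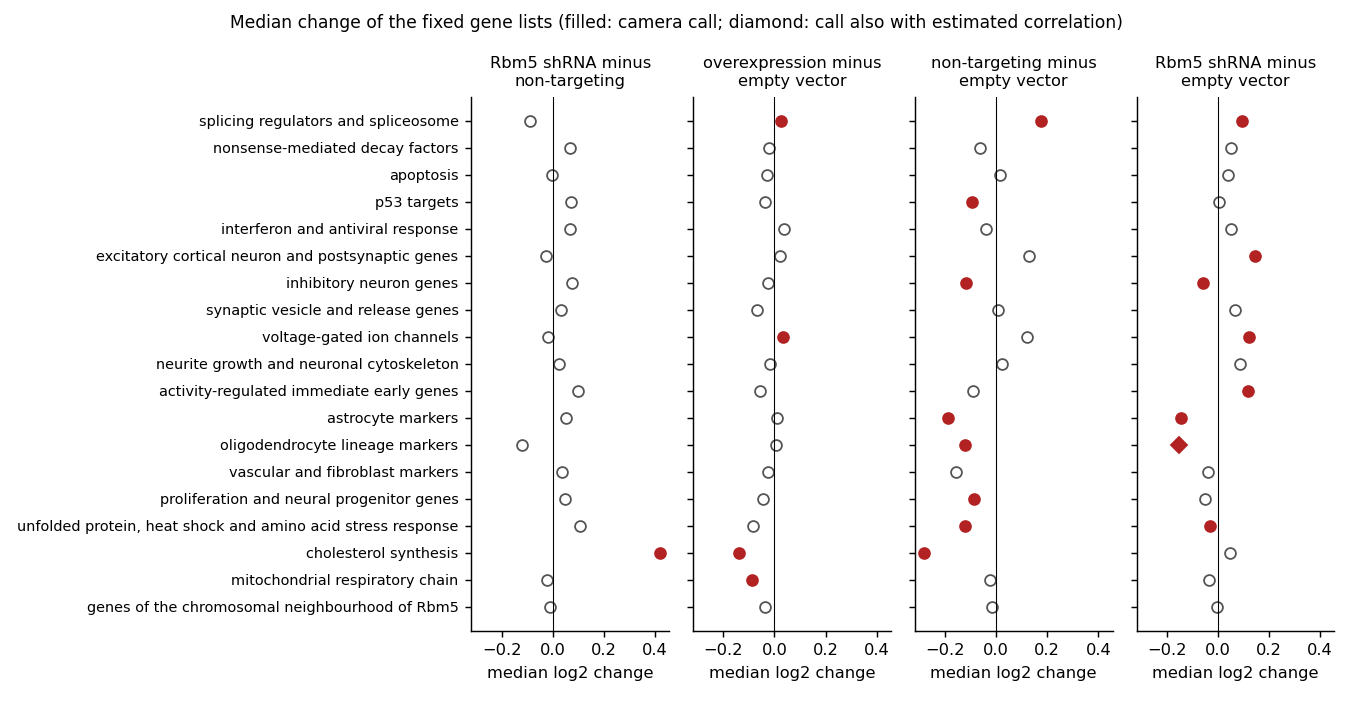
Median log2 change of the 19 tested gene lists in 4 comparisons, 1 point per list, filled where camera called the list and drawn as a diamond where the call held with an estimated correlation. Cholesterol synthesis lies at 0.421 in the knockdown and at -0.284 between the control vectors, and the single diamond is the oligodendrocyte lineage list in Rbm5 shRNA minus empty vector at -0.151.

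The next question was what changed when Rbm5 was raised. The overexpression changed Rbm5 and no other transcript cluster past the threshold in limma. An unadjusted p under 0.05 was found for 431 clusters where chance gives 1449, and groups did not overlap for 0.759% where chance gives 2.86%. In simulated arrays the same fit called 79.1% of clusters changed by 1 on the log2 scale and 46.3% of those changed by 0.5. The simulated noise was independent between clusters and equal between groups. On the real arrays the first component had an SD of 39 with the empty vector and 35.5 with the overexpression, against 13.7 and 11.1 in the shRNA groups. The simulated shares may therefore be too high for this comparison. The clusters with the smallest p besides Rbm5 were Pcdhga4, a clustered protocadherin (0.28, SE 0.093), Creg2 (0.24, SE 0.079) and the receptor Gpr75 (0.22, SE 0.077) on the positive side, and Fitm2 (-0.26, SE 0.088), the G protein subunit Gng4 (-0.37, SE 0.12), Rpl37al2 (-0.38, SE 0.13) and Rpl22l3 (-0.48, SE 0.17) on the negative side, each with an adjusted p of 1.

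Camera called 4 lists in the overexpression, none of which kept its call with an estimated correlation. The mitochondrial respiratory chain (median -0.090, adjusted p = 0.000418, 33 of 37 members negative) and cholesterol synthesis (median -0.14, adjusted p = 0.00856, all 19 members negative) were shifted downward. Voltage-gated ion channels (median 0.035, adjusted p = 0.0153, 26 of 37 members positive) and splicing genes (median 0.024, adjusted p = 0.0376, 42 of 69 positive) were shifted upward. For each of them the test gave an adjusted p = 0.808 with an estimated correlation. In the order given, fry gave an unadjusted p of 0.393, 0.448, 0.374 and 0.625. No member of any list passed over all genes or when adjusted over the list alone. The members with the smallest p were Ndufa9 (-0.24), Ndufv1 (-0.30), Uqcrc1 (-0.29) and Atp5d (-0.29) for the respiratory chain, Dhcr7 (-0.34), Fdft1 (-0.28), Msmo1 (-0.22) and Fdps (-0.14) for cholesterol synthesis, Kcna4 (0.24), Kcna1 (-0.22), Kcnc1 (0.13) and Kcnd3 (0.11) for ion channels, and Tial1 (0.21), Rbm39 (0.20), Hnrnpa2b1 (0.13) and Srsf11 (0.11) for splicing. When the control-probe difference entered the fit as a covariate, an alternative added after seeing the data, all 4 lists lost their call, with medians of -0.025 for the respiratory chain, -0.017 for cholesterol synthesis, 0.019 for ion channels and 0.026 for splicing genes. Without empty vector array 4 or overexpression array 3 no list was called. The other 15 lists had adjusted p from 0.0849 to 0.603, and the median, mean and camera direction differed in sign for 5 of them.

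The control groups were compared to see how far the vector backgrounds differed. Here the vector, with its hairpin and fluorescent protein, and the dose of virus cannot be told apart. Rbm5 shRNA cultures, which received the same dose as the non-targeting cultures, differed from the empty vector in 38 clusters, a comparison added after seeing the data. Non-targeting shRNA differed from the empty vector in 1289 clusters, 877 higher and 412 lower, so that 68% were higher, but 42.5% after quantile normalization and 39.6% after median centring. The largest named rises were Cdh12 (1.99, SE 0.19, adjusted p = 0.000179), Txnip (1.76, SE 0.33, adjusted p = 0.0102) and the ephrin receptor Epha3 (1.49, SE 0.17, adjusted p = 0.000649), followed by Gpc2 (1.47), Rgs13 (1.46), the osmotic stress factor Nfat5 (1.42, but 0.92 and adjusted p = 0.0692 on a further cluster), Drd2 (1.41), Hs6st2 (1.40), St6galnac5 (1.36), the neuropeptide Nts (1.31), Pcdh9 (1.30) and Arrdc3 (1.29). The largest falls were Uchl3 (-2.21, SE 0.18, adjusted p = 6.74e-05, and -0.95 on its further cluster), Reln, a glycoprotein secreted by some cortical interneurons (-1.91, SE 0.22, adjusted p = 0.000796), and Pfn2 (-1.87, SE 0.17). Tprg1l (-1.82), Tmbim6 (-1.73), Gpr137c (-1.72), Ccdc6 (-1.63), Igfbp5 (-1.61), Mmp24 (-1.61), Cpne8 (-1.58), the calcium pump Atp2b4 (-1.57) and Fam3c (-1.56) fell as well. Groups did not overlap for 21.6% of clusters where chance gives 5.71%. Without non-targeting array 1, 2 or 3 the count was 371, 391 or 594, without empty vector array 1, 2, 3 or 4 it was 699, 620, 2027 or 594, and the calls of Txnip, St6galnac5, Nts and Atp2b4 ended without non-targeting array 1.

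These calls mirrored those of the knockdown. Of the 729 knockdown calls besides Rbm5, 470 were also called between the control vectors, 469 of them with the opposite sign. Both comparisons use the non-targeting arrays. Simulations without any effect gave an overlap of 0, but with hardly anything to call they cannot show what the shared arrays add. Independent sets would share 15.8. With n = 3 the non-targeting arrays could not be divided into sets of at least 2, so part of the excess over 15.8 may come from the shared arrays. Across clusters, which are not independent replicates, r was -0.829 against a simulated -0.535 and the covariance -0.0838 against -0.0247.

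Camera called 8 lists between the control vectors, and none kept its call with an estimated correlation (adjusted p from 0.643 to 0.783). Fry gave an unadjusted p of 0.00434 for oligodendrocyte lineage markers, 0.00602 for splicing genes and 0.0226 for p53 targets. For the other called lists its p ran from 0.062 to 0.395. Splicing genes were shifted upward with non-targeting shRNA (median 0.18, adjusted p = 0.000659, 55 of 69 positive): 8 rose over all genes and 17 when adjusted over the list alone, with Rbfox1 (0.63), Khdrbs2 (0.53), Tial1 (0.47) and the spliceosome component Sf3b1 (0.47) as examples. Cholesterol synthesis was shifted downward (median -0.28, adjusted p = 0.00112), with all 19 members negative and Lss (-0.71) past the threshold over all genes and when adjusted over the list alone, though a further Lss cluster did not pass (-0.61, adjusted p = 0.0552). Ebp (-0.57), Nsdhl (-0.80) and Fdps (-0.37) did not pass. Of 18 inhibitory neuron genes (median -0.12, adjusted p = 0.00901) Reln fell over all genes and 2 fell when adjusted over the list alone, while Dlx5 (-0.44), Slc32a1 (-0.36) and Npy (-0.73) did not pass. Of 23 p53 targets (median -0.096, adjusted p = 0.0123) 3 fell and 1 rose over all genes, and 6 fell and 2 rose when adjusted over the list alone. Zmat3 (-0.80), Cdkn1a (-0.67) and Ccng1 (-0.65) were the falls, and Ccng2 (0.64) the rise. Single left-out arrays ended the calls of Rbfox1, Khdrbs2, Tial1, Sf3b1, Lss, Ccng1 and Ccng2, and quantile normalization those of Tial1 and Ccng2.

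Camera at the preset correlation also called lists of markers of other cell types between the control groups. These calls did not hold with an estimated correlation (adjusted p = 0.769 for astrocyte and 0.643 for oligodendrocyte lineage markers). Astrocyte markers (median -0.19, adjusted p = 0.00505, 17 of 21 negative) and oligodendrocyte lineage markers (median -0.12, adjusted p = 0.00832, 10 of 13 negative) were lower as lists with non-targeting shRNA. No member of either passed over all genes, and 0 and 2 fell when adjusted over the list alone. Glul (-0.55, and -0.055 on a further cluster), Apoe (-0.41), Ndrg2 (-0.31) and Agt (-0.28) were the leading astrocyte members, and Pdgfra (-0.49), Olig1 (-0.60), Bcas1 (-0.23) and Gpr17 (-0.40) the leading oligodendrocyte members. The unfolded protein and amino acid stress list (median -0.12, adjusted p = 0.00832) held Slc7a11 (-0.94), Psat1 (-0.51), Ddit3 (-0.33) and Trib3 (-0.27), and the proliferation list (median -0.087, adjusted p = 0.0468, a call lost after quantile normalization or median centring) Sox2 (-0.42), Nes (-0.38), Hes1 (-0.33) and Cenpe (0.39), with no member of either past the threshold over all genes or when adjusted over the list alone. In lists that camera did not call, with adjusted p from 0.17 to 0.773, 12 members rose and 7 fell over all genes. Of 37 ion channel genes 3 rose and 2 fell (5 up and 2 down when adjusted over the list alone), among them Kcnd2 (0.52) and Scn3b (-0.93). Of 31 neurite genes 3 rose and 2 fell (5 up and 2 down when adjusted over the list alone): Robo2 (0.56), Robo1 (0.48) and Cntn2 (0.44), named after their values were seen, and Gap43 (-0.65) and Cntn1 (-0.60). Of 18 immediate early genes 3 rose and none fell (5 up and 1 down when adjusted over the list alone), among them Fosl2 (0.74) and Nr4a3 (0.68). Gria4 (0.81) rose and Homer1 (-0.64) fell among excitatory genes (4 up and 2 down when adjusted over the list alone), Syt4 (0.61) rose and Sv2b (-0.57) fell among synaptic vesicle genes (2 up and 2 down), Dcn (0.89) rose among vascular and fibroblast markers (1 up and 1 down) and Hyal1 (-0.47) fell among the neighbours of Rbm5 (1 down). After quantile normalization 3 of the 12 rises and 6 of the 7 falls kept their call, after median centring 3 and 7, and the rise of Syt4 was 0.017 after quantile normalization. Single left-out arrays ended the calls of Gria4, Kcnd2, Cntn1, Gap43, Nr4a3, Syt4, Sv2b, Dcn and Hyal1.

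The last question was whether lowering and raising Rbm5 acted in opposite ways. The effects differed for 211 clusters, 125 with a higher and 86 with a lower change in the knockdown, by -4.00 (SE 0.14, adjusted p = 1.31e-08) for Rbm5. Such a difference does not by itself show opposite action, since it also arises where only the knockdown changed. Besides Rbm5 no cluster passed in the overexpression. For genes such as Uchl3 and Cdh12 the knockdown change lay mainly in the non-targeting arrays, as given above. The share with a higher change, 59.2%, was 77.3% after quantile normalization. It was 47% with array weights and 46.9% with a control-probe covariate (added after seeing the data). Uchl3 (2.14, and 0.93 on its further cluster), Rgs4 (1.98), Pfn2 (1.96), Fam3c (1.95), Rab4a (1.89), Tmbim6 (1.80), Tprg1l (1.75), Ipo5 (1.66), Sec23a (1.65), Sema3c (1.62), Ccdc6 (1.60) and the glucose transporter Slc2a3 (1.59) had the largest positive differences. Cdh12 (-1.61), Slc25a2 (-1.58), Mzt2b (-1.58), Ptpn4 (-1.54), Alcam (-1.49), Zfp120l1 (-1.43), Gpc2 (-1.36), Drd2 (-1.31), Rgs13 (-1.27), Epha3 (-1.26) and Klhl7 (-1.23) had the largest negative differences after Rbm5. Rbm6 (-0.26, adjusted p = 0.366) and Rbm10 (0.12, adjusted p = 0.805) did not pass. As lists, cholesterol synthesis differed upward (median 0.56, camera adjusted p = 2.79e-05) and splicing genes downward (median -0.11, adjusted p = 0.0359), both with an adjusted p = 0.953 with an estimated correlation, and no member of either passed over all genes or when adjusted over the list alone. Fry gave an unadjusted p of 0.0896 for cholesterol synthesis, 0.189 for splicing genes and 0.0277 for p53 targets. Of the p53 targets Cdkn1a (0.76) and Zmat3 (0.87) passed over all genes and 4 members when adjusted over the list alone (list adjusted p = 0.0504), and Sv2b (1.01) and Scn3b (1.13) were the only members of the synaptic vesicle and ion channel lists to pass. These members were named after their values were seen. No gene besides Rbm5 passed in both the knockdown and the overexpression. Across 28975 clusters, which are not independent replicates, the changes in the knockdown and in the overexpression were correlated at r = -0.416 and rho = -0.374, and r was -0.17 without empty vector array 2. Leaving out single arrays moved the count of 211 to between 62, without non-targeting array 1, and 343, without empty vector array 3. Of 24 named clusters called here, 12 lost their call in at least 1 such case, among them Rgs4, Epha3 and Ptpn4.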

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

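The tests of the left-out arrays, of the control-probe covariate and of the divided empty vector arrays were chosen only after the results they bear on had been seen, while the regroupings of the arrays were set before.

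Among 123 sets of replicate values of named genes and array measures examined for a single deviating array, 1 passed the critical gap ratio of a Dixon test where 6.2 would by chance. Pfn2 on empty vector array 2 was at 14.7 against 14.34 to 14.39 on the other arrays of its group, a gap ratio of 0.865. The array takes part in the change of Pfn2 between the control vectors (-1.87), which kept its call without it. In the knockdown it does not enter the change of Pfn2, only its SE through the joint fit, and that call also held without the array.

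The knockdown calls mirrored those between the control vectors. Clusters were selected on 2 pairs of arrays and read on the pair left out: the non-targeting array then held at least 80% of the distance between the groups and the Rbm5 shRNA array at most 20%. Noise in the selecting arrays would not carry over to a left-out array, and a loss of Rbm5 acting on all called clusters would put the distance into the knockdown arrays. A vector or dose acting alike in both shRNA groups would move Rbm5 shRNA arrays as well. Over clusters called between the control vectors without 1 non-targeting array, Rbm5 shRNA arrays shared at most 10.2% of the shift of the array left out. The shares, against the overexpression arrays, were 5.67%, 10.2% and 7.65% over 371, 391 and 594 clusters. These readings take the effects of Rbm5 loss and of vector or dose as separate. A vector or dose effect that the loss of Rbm5 cancels would give the same values. No group lowers Rbm5 without the shRNA vector, so the tests cannot decide on that. A state particular to the non-targeting cultures, whether from the hairpin sequence, the virus batch or the culture, may account for most calls, and a further control hairpin would test that hypothesis.

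The knockdown and overexpression effects were negatively correlated across clusters, r = -0.416. With the control-probe difference as a covariate r was -0.218, a value at which an array quality axis and other sources cannot be told apart. An opposite response to Rbm5 dose stays open too: with 2 empty vector arrays used to select clusters changed against both controls and the other 2 to read the overexpression, at most 6 clusters were selected in any of 6 divisions, too few to decide (6 of 6, 2 of 2, 1 of 1 and 1 of 2 moved the opposite way, and 2 divisions selected none). With all 4 empty vector arrays in both steps, which draws such changes to the same sign, 14 of 26 (53.8%) moved the opposite way against 63.7% of the other 703 calls. Of 100 regroupings drawn from 350, 8 gave a correlation as large in size, and the highest other was 0.574, so chance is not excluded.

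With the control-probe covariate 0 of the 4 lists called in the overexpression kept the call, but the lists differed in what became of the shift. The median of cholesterol synthesis went from -0.14 to -0.0169 (12.2% left, adjusted p = 0.199) and that of the respiratory chain from -0.090 to -0.0248 (27.6% left, adjusted p = 0.171), so variation in array quality is a candidate explanation of these 2 shifts. Ion channels kept 53.1% (0.0188, adjusted p = 0.898) and splicing genes 108% (0.0263, adjusted p = 0.376), and for these lists the array-to-array axis and other sources cannot be told apart. The splicing call ended because the other genes moved: the mean t of its members was 0.241 without and 0.348 with the covariate, that of all other genes -0.1 and 0.137, and the mean change of the list was 0.020 (SE 0.048) and 0.029 (SE 0.050). Of 35 regroupings, 16 called as many lists and the highest other called 10, so chance is not excluded for any of them.

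Regroupings of the arrays gave the following counts. For the knockdown 1 of 10 called as many clusters (730 in the real grouping, 0 at most in another) and 7 of 10 as many lists (1 real, 4 at most), and 10 splits are too few for a share under 0.05. For the control vectors 1 of 35 called as many clusters (1289 real, 998 at most in another, a share of 2.86%), and 9 of 35 as many lists (8 real, 10 at most). The regrouping with 998 calls put only empty vector array 3 beside the non-targeting arrays, and no other called any cluster. Putting empty vector array 1, 2 or 4 there instead keeps as much of the real contrast, yet gave 0 calls. The regrouping with 998 calls had a control-probe difference of 0.306, rank 5 of 35 by size, against -0.115 in the real grouping. Whether the quality axis contributed to its count was not tested. For the difference of effects 7 of 100 drawn from 700 called as many (211 real, 5068 at most), and for the overexpression 3 of 35 (1 real, 4633 and 2028 in the others). In the overexpression, these counts several times the real one point to structure among the samples other than the treatment. For the difference of effects they cannot show this. A regrouping that keeps the real knockdown groups and changes only the overexpression groups still holds the difference between the shRNA groups. Those with 5068 and 2188 calls were of this kind, while 1 with 3041 calls was not. The regroupings with 4633 and 2028 calls had the largest and next largest control-probe differences of the 35, -0.561 and 0.485 against 0.169 in the real grouping, so the same quality axis may underlie them.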

How the results depend on the processing

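The control-probe covariate, the empty vector as the control and the call against both controls were chosen only after the results were seen, and the other alternatives before.

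The change of Rbm5 held throughout: it ran from -2.53 to -2.16 in the knockdown over 26 alternatives and from 1.47 to 1.58 in the overexpression over 25, and the overexpression called 1 cluster in all 27. Of the named calls, 27 of 36 held in every alternative chosen beforehand in the knockdown, 25 of 45 between the control vectors and 12 of 24 in the difference of effects. The knockdown call set depended on the control used, and list calls on the correlation assumed between genes. Tests of the control dependence, the overexpression lists and the correlation are given above. For the other results the cause was not tested.

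For the knockdown, the count of 730 was 1221 at an adjusted p under 0.10, 427 without a filter, 2070 with array weights, 1731 with the control-probe covariate, 38 with the empty vector as the control and 27 against both controls. The difference of effects (211) was 442 at an adjusted p under 0.10, 81 without a filter, 418 with only clusters of 1 gene symbol, 326 after quantile normalization, 591 with array weights and 503 with the control-probe covariate. The control vectors (1289) gave 2446 at an adjusted p under 0.10, 767 with a 1.5-fold limit, 799 on only the arrays of the 2 groups compared, 691 without a filter, 3909 with array weights and 3020 with the control-probe covariate. Lists called fell to 0 with camera at an estimated correlation in the knockdown (from 1), the overexpression (from 4) and the control vectors (from 8). The knockdown called 4 lists with no filter and 8 with the empty vector as the control, and the overexpression 0 with the control-probe covariate. The correlation of the effects (-0.416) was -0.324 with no filter, -0.195 with only clusters of 1 gene symbol and -0.218 with the control-probe covariate.

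With the empty vector as the control these, called against at least 1 control, had the opposite sign: Tprg1l -0.129, Tmbim6 -0.11, Mmp24 -0.0938, Cpne8 -0.086, Zmat3 -0.0152, Drd2 0.151, Rgs13 0.123, Cdh12 0.55, Txnip 0.244, Fosl2 0.149, and the medians of the list of splicing regulators and spliceosome (0.0955), inhibitory neuron genes (-0.0583), astrocyte markers (-0.145), the unfolded protein, heat shock and amino acid stress response (-0.0322), excitatory genes (0.146) and ion channels (0.123). Called against neither, Rbm6 (0.0149) and the medians of apoptosis (0.0379), vascular (-0.0394) and proliferation genes (-0.0498) also turned.

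The share of calls that were higher was 53.4% in the knockdown, 71.8% after quantile normalization and 76.1% after median centring, against 59.2%, 77.3% and 80.6% in the difference of effects and 68%, 42.5% and 39.6% between the control vectors. In the knockdown it was 39.2% on only the arrays of the 2 groups compared, 40.4% with the covariate and 42.9% with array weights. In the difference of effects it was 46.9% with the covariate and 47% with array weights, so the majority direction turned there too. Centring moved the median of all clusters from -0.084 to 0.0401 in the difference of effects and from 0.0619 to -0.0385 between the control vectors, so directions are relative to the deposited scaling.

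Leaving out single arrays gave 310 (without non-targeting shRNA replicate 2) to 859 (without Rbm5 overexpression replicate 1) clusters in the knockdown, 62 (without non-targeting shRNA replicate 1) to 343 (without empty vector replicate 3) in the difference of effects and 371 (without non-targeting shRNA replicate 1) to 2027 (without empty vector replicate 3) between the control vectors. Lists ran from 1 (without non-targeting shRNA replicate 1) to 2 (without Rbm5 shRNA replicate 2) in the knockdown, 0 (without empty vector replicate 4) to 7 (without empty vector replicate 3) in the overexpression and 6 to 9 between the control vectors, and the correlation from -0.47 (without empty vector replicate 1) to -0.17 (without empty vector replicate 2). The count for the difference of effects moved more than 1.5-fold without any non-targeting array (62, 64, 80), any Rbm5 shRNA array (94, 135, 75), any empty vector array (104, 107, 343, 85) or overexpression replicate 2 (104).

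With the replicate number within each experiment as a block, 7 blocks in all, the knockdown called 843 clusters (595 of the 730 among them), the overexpression 1 (Rbm5) and the difference of effects 211 (142 of the 211 among them), and r was -0.416. The knockdown called 1 list (cholesterol synthesis) and the overexpression 4, where splicing genes lost and the stress response gained a call. Pairing by replicate number was not borne out by the arrays: correlations of paired deviations were 0.226, 0.195 and -0.0957 in the knockdown and -0.358, -0.219, 0.778 and 0.458 in the overexpression, and arrays matched their own number best in both directions only for numbers 1 and 2 of the knockdown and 3 and 4 of the overexpression. This fit gives no value for the control vectors, which lie in different blocks.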

Other observations

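All tests in this section were chosen only after the results had been seen.

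Averaged over 13 members, oligodendrocyte lineage markers were lower on the 6 shRNA arrays than on the 8 other arrays. The difference was -0.233 (exact permutation p = 0.000999, adjusted p = 0.0127 over 19 lists). Group means were 7.695 ± 0.069 (SD, n = 3) with non-targeting shRNA and 7.603 ± 0.093 (n = 3) with Rbm5 shRNA. They were 7.887 ± 0.072 (n = 4) with the empty vector and 7.876 ± 0.087 (n = 4) with the overexpression. The arrays overlapped, with the highest shRNA array at 7.754 and the lowest other array at 7.75. The permutation test pools the shRNA groups and does not test either alone. For non-targeting shRNA against the empty vector, the camera call did not hold with an estimated correlation (adjusted p = 0.643). No member passed over all genes in that comparison. Excitatory neuron and postsynaptic genes were higher by 0.137 with the shRNA vectors (exact permutation p = 0.00133, adjusted p = 0.0127). Astrocyte markers (-0.167, adjusted p = 0.068) and inhibitory neuron genes (-0.229, adjusted p = 0.0878) did not pass. Vector type, dose of virus and the fluorescent reporter change together here.

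Between Rbm5 shRNA and the empty vector the oligodendrocyte list kept its call with an estimated correlation (median -0.15, camera adjusted p = 3.65e-07, and adjusted p = 0.0224 with an estimated correlation). Pdgfra, a marker of oligodendrocyte precursors (-0.92, SE 0.15, adjusted p = 0.0308), and Bcas1, found in newly forming oligodendrocytes (-0.56, SE 0.083, adjusted p = 0.0151), fell over all genes, and 3 members fell when adjusted over the list alone. Gpr17 (-0.87, adjusted p = 0.0742) did not pass over all genes, and in the knockdown against non-targeting shRNA Pdgfra (-0.43, adjusted p = 0.225) and Bcas1 (-0.33, adjusted p = 0.0761) did not pass. The other lists called here were astrocyte markers (median -0.145, adjusted p = 7.21e-05), inhibitory neuron genes (-0.058, adjusted p = 0.0233) and the stress response (-0.032, adjusted p = 0.0497) downward, and excitatory genes (0.15, adjusted p = 0.0206), splicing genes (0.096, adjusted p = 0.0206), ion channels (0.12, adjusted p = 0.0206) and immediate early genes (0.12, adjusted p = 0.0417) upward. None of these 7 kept the call, with adjusted p from 0.686 to 0.806 with an estimated correlation. Fry gave an unadjusted p of 0.000245 for the oligodendrocyte list and from 0.0212 to 0.544 for these 7.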
